A study of Homo sapiens with 4 samples.

How the data were processed

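The series compared an esophageal cancer cell line, TE1, with its paclitaxel-resistant derivative, RTE1P, with 2 arrays per line. Groups came from the source names in the labels. Total RNA was labelled with Cy3 and hybridised to a single-colour Agilent array of design 014850, per the labels' protocols and the file headers. The deposited intensity values were made with Agilent Feature Extraction, version 10.7.3.1 with protocol GE1_107_Sep09 per the file headers, while the submitters' processing notes give version 9.5.1. The intensity used was the processed signal, which per the file headers is background-subtracted and corrected for trends over the array, with a small positive value in place of signals near 0, and not scaled between arrays. The authors' deposited value table of the series equals this intensity on every spot, with a largest difference of 0 on each array, so as an alternative it stands for values without scaling. Its column medians were 160.2 and 146.1 for TE1 and 199.0 and 181.9 for RTE1P; its scale is linear and it was not centred.

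All 4 arrays were read from 1 slide with 1 scan time, so slide was not tested as a batch, and position on the slide coincides with the line. The 75th percentile of the processed signal was 1412 and 1221 on the TE1 arrays and 1534 and 1282 on the RTE1P arrays, and no spot was saturated. Between 66 and 87 spots per array carried an outlier flag. The number of arrays limits the precision. No spot had identical values on both arrays of a line, so the arrays were kept as separate replicates.

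In the main setting, control spots were left out, each array was divided by its 75th percentile, signals under 1 were set to 1, and log2 was taken. Log2 levels are given relative to the 75th percentile. Spots flagged as outliers were set to missing, spots of a probe were averaged, and a probe needed values on all 4 arrays, which left out 11 probes. A probe was tested if it was well above background on both arrays of at least 1 line, which held for 30274 of 41000 probes. Probes were named through the RefSeq accession in the files and a RefSeq gene table of assembly GRCh38.p14, without versions on both sides: 26222 probes had 1 symbol and 14778 are unnamed here, 1093 of which passed the test. A gene was represented by its tested probe with the highest mean signal. In 6 genes another probe passed in the opposite direction. Of the coordinates in the table only the order of genes was used.

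Lines were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the group alone, 2 residual degrees of freedom and 4.70 in total after moderation, two-sided, with Benjamini-Hochberg adjustment over all tested probes. At this step 4485 probes passed, 2864 higher and 1621 lower in RTE1P. Gene lists were tested with camera at a preset correlation of 0.01 on genes, adjusted over the 34 lists. As an alternative the correlation was estimated. That test rests on the 2 residual degrees of freedom, so hardly any list can pass it after adjustment over 34 lists. For each list the median was also ranked among 10000 random lists matched on mean signal in 50 bins. The genes named were fixed by a rule before the data were examined: ABCB1; the 12 largest rises and the 12 largest falls among passing genes above background on all 4 arrays; the 5 with the largest bound in each direction among passing genes above background in 1 line; and up to 4 members per gene list, those with the largest change among members that pass, or 2 members where none passes. Not every gene allowed by the rule is named, and genes outside it are said to be chosen after their values were seen.

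A scan in gene order took the median log2 fold change of 15 neighbouring genes over 14696 genes and compared it with 1000 shuffles of the fold changes over all genes. The scan was added after the rise around ABCB1 was seen. The block around ABCB1 is the run of windows above the shuffles' upper limit of 0.86, trimmed to its first and last gene with a rise of at least 2-fold.

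The steps were tested on simulated data. For RTE1P against TE1, arrays were drawn for 30274 probes, 50 of them changed by each fold size. limma called 0% of the 1.5-fold changes, 0% of the 2-fold changes, 78% of the 4-fold changes and 94% of the 8-fold changes, with 5 false calls. A smaller share of probes was changed there than passed in the real arrays, where genes with changes under 2-fold also passed. camera called a simulated list of 25 genes shifted by 0.5 (adjusted p = 1.28e-18) and 0 of 34 other simulated lists. The scan found 100% of the inner windows of planted blocks of 30 genes shifted by 1 on the log2 scale over 14696 genes, and 0 windows elsewhere; a regional rise below the upper limit cannot be seen by the scan.

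The alternatives fixed before the data were examined were a normexp background with offset 50, quantile normalization, median scaling, the deposited values without scaling, no filter on dim probes, a filter on all 4 arrays, a floor of 32, flagged spots kept, the mean of a gene's probes, eBayes with trend and robust, the replicate number as a block, each array left out in turn, a threshold of 0.01, camera with an estimated correlation and fry. The files used here hold the median but not the mean spot signal, so normexp was run on the median signal and the local background median. Cyclic loess and the count without the genes of the chromosome 7 block were added after seeing the data. Figures were drawn with matplotlib.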

Results

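Gene expression was measured in TE1, a human cell line from an esophageal squamous cell cancer, and in RTE1P, a line derived from TE1 that is resistant to paclitaxel. Paclitaxel is a taxane that binds and stabilises microtubules. Total RNA of each line was labelled with the dye Cy3 and hybridised to 2 single-colour Agilent whole-genome arrays, so the comparison was 2 arrays against 2 arrays. The labels do not say whether the drug was present at harvest, and do not say whether the 2 arrays of a line came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Each array held 43376 gene spots, of which 74.3% and 74.9% on the TE1 arrays and 73.2% and 78.7% on the RTE1P arrays were well above background. Across probes, the log2 signals correlated at r = 0.9935 between the TE1 arrays and at r = 0.9951 between the RTE1P arrays. Correlations across lines were lower, from 0.9778 to 0.9834. Probes are not independent replicates. The SD of the difference between arrays was 0.353 within TE1 and 0.285 within RTE1P, and 0.536 to 0.676 across the lines.

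The comparison asked which transcripts differ between the resistant line and its parent. ABCB1, the drug efflux pump P-glycoprotein, which transports taxanes, showed the largest rise among genes measured on all 4 arrays. Its scaled log2 signal was -4.98 ± 0.113 (SD, n = 2) in TE1 and 0.56 ± 0.168 (SD, n = 2) in RTE1P, a 46.5-fold rise (log2 fold change 5.54, SE 0.139, limma adjusted p = 0.00198). Its TE1 level lay not far above the lowest signals well above background on those arrays, -6.15 and -5.78. The size of the fold may therefore depend on the background subtraction. ABCB1 lies in a block of 48 neighbouring tested genes on chromosome 7, of which 44, ABCB1 included, rose and 0 fell. Of 24 sterol synthesis genes 15 rose and 1 fell, and of 28 genes of the unfolded protein and amino acid stress response 16 rose and 0 fell. Both lists passed camera at the preset correlation. Neither did with an estimated correlation (camera adjusted p = 0.503 for each), a test that has only 2 residual degrees of freedom. Among genes above background on all 4 arrays, the largest falls were those of SRGN, which encodes the proteoglycan serglycin, and of ABCG2, another drug efflux pump, which fell 29.7-fold and 13.4-fold.

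In all, 2386 of 14711 tested genes passed an adjusted p of 0.05 in the limma fit, 1468 higher and 918 lower in RTE1P. Of these, 787 differed at least 2-fold by fitted values, 596 upward and 191 downward, or 582 and 186 with genes measured in 1 line only set at their bounds. With a normexp background, whose offset of 50 shrinks the folds of dim probes, these were 363, 243 and 120. The rises of at least 2-fold were 370 with quantile normalization and 359 with cyclic loess. The split depended on signal and on scaling. With genes ranked by mean signal into 4 bins of equal size, 647 rose and 90 fell in the dimmest bin, with a median log2 fold change of 0.54, and 106 rose and 336 fell in the brightest bin, with a median of -0.17. The share of passing genes that rose was 61.5%, against 51.8% with quantile normalization, 53.4% with cyclic loess, 30.9% with median scaling, 84% without scaling and 52.5% with a normexp background. The fit without scaling had 60500 total degrees of freedom against 4.70. It thus treated the spread between arrays as nearly known, and its p-values are not comparable with the others. With 2 arrays per line the precision was limited. In a fit with 1 array left out, the spread came only from the line that kept 2 arrays. The total degrees of freedom were 3 and 3.29 without RTE1P replicate 1 and 2, and 5.86 and 5.79 without TE1 replicate 1 and 2. The number of arrays therefore does not explain how these fits differ from each other. Without RTE1P replicate 1 or without RTE1P replicate 2, no gene passed in limma, although 3759 and 3216 genes had an unadjusted p under 0.05. Without TE1 replicate 1 the count was 1083, and without TE1 replicate 2 it was 3428.

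**Figure D1:**
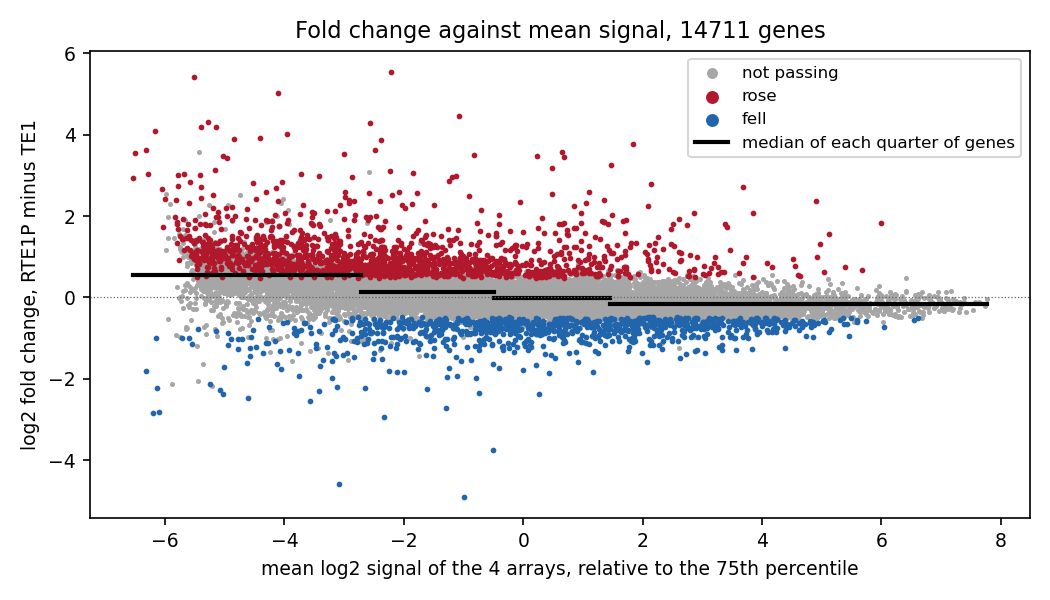
Log2 fold change of each tested gene (vertical axis, RTE1P minus TE1) against its mean log2 signal over the 4 arrays (horizontal axis), with risen genes in red, fallen genes in blue and the others in grey. Black bars mark the median of each of 4 bins of genes by signal, which lies at 0.54 in the dimmest and at -0.17 in the brightest bin.

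After ABCB1, the largest rises among genes above background on all 4 arrays were those of SCD, which encodes stearoyl-CoA desaturase (22.1-fold, log2 fold change 4.46, SE 0.123), and HSD17B2, a steroid dehydrogenase (19.5-fold, SE 0.136 on the log2 scale). KRT23, a type I keratin, rose 13.6-fold, the cytokine gene TNF 11.6-fold and SAA1, an acute-phase protein gene, 11.2-fold. The remaining 6 of the 12 largest rises, RUNDC3B, CROT, ELAPOR2, ADAM22, TMEM243 and DBF4, all lie in the chromosome 7 block. The 12 largest falls also included DIO2, an iodothyronine deiodinase (7.72-fold), PRSS3, a trypsinogen (6.54-fold), and KRT17, a basal keratin (5.20-fold). EPGN and EREG, which encode the EGF receptor ligands epigen and epiregulin, fell 4.96-fold and 4.69-fold. The neurotensin receptor gene NTSR1 fell 4.59-fold. CFAP97, MYPN, SPTLC3 and CD68 completed the 12, with falls from 3.93-fold for CD68 to 5.12-fold for CFAP97.

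**Figure D2:**
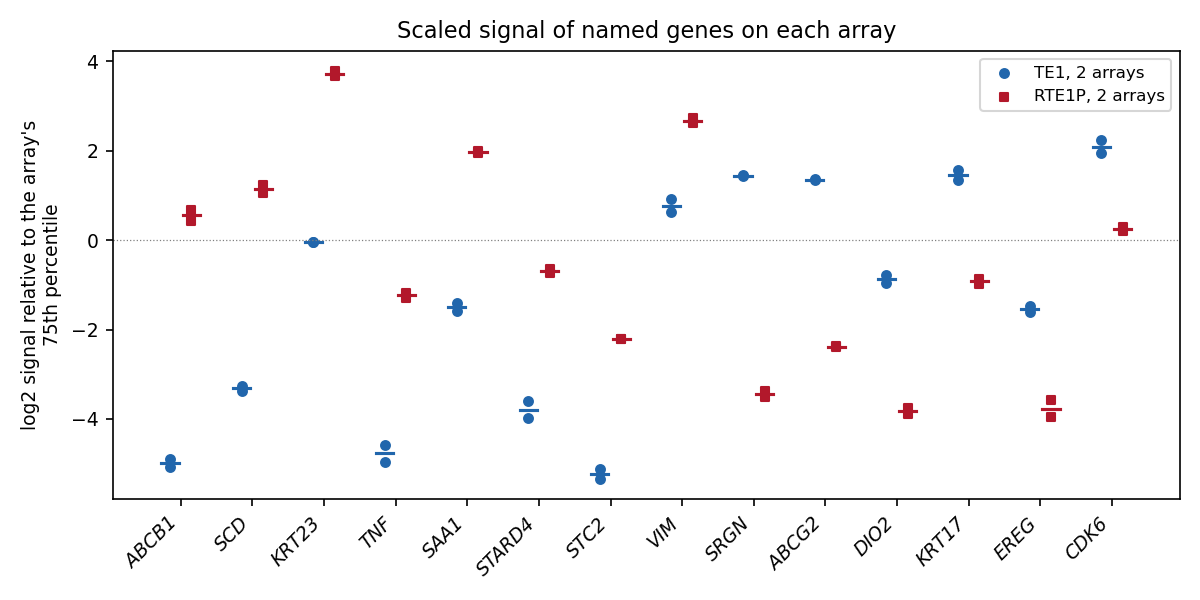
Log2 signal of 14 genes relative to each array's 75th percentile (vertical axis), with TE1 arrays as blue circles, RTE1P arrays as red squares and short bars for the mean of 2 arrays. For ABCB1 the TE1 mean is -4.98 and the RTE1P mean is 0.56; for SRGN they are 1.45 and -3.45. CDK6 was added after its values were seen.

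Some passing genes were well above background in only 1 of the lines, 99 of them in RTE1P only and 16 in TE1 only. Their folds are given as lower bounds, taken against the higher of the dim probe's own signal and the lowest signal well above background on the same array. These bounds allow for background only and do not include the spread between arrays. CLIC5, a chloride channel protein gene, was at least 20.8-fold higher in RTE1P. SELENOP, which encodes a secreted selenoprotein, was at least 8.95-fold higher, the cancer-testis gene MAGEB6 at least 8.42-fold, and the chemokine genes CCL20 and CCL2 at least 7.60-fold and 7.21-fold. In the other direction COL4A6, a basement membrane collagen gene, was 24.2-fold lower in RTE1P. This is its fitted fold (log2 fold change -4.59, 95% interval -4.97 to -4.22), since its RTE1P signals lay above that lowest signal. STC1, which encodes stanniocalcin, was at least 3.04-fold lower, the muscle creatine kinase gene CKM at least 2.83-fold lower, and XRCC2, a recombination gene, at least 2.43-fold lower.

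The rise at chromosome 7 was regional. In the gene order of the GRCh38.p14 assembly, used for neighbourhood only because the arrays were annotated on another build, the block ran from RCC1L to SRI. Of its 48 tested genes 44 rose, 0 fell and 41 rose at least 2-fold by fitted values, and the median log2 fold change was 2.03, or 4.07-fold. CD36, the single gene of the block measured in RTE1P only, was named after its values were seen. With CD36 set at its bound of 1.87-fold, 40 rose at least 2-fold and the median was 2.00. The highest rises lay around ABCB1, with RUNDC3B at 14.7-fold, CROT, a peroxisomal carnitine acyltransferase gene, at 12.2-fold, and DBF4, which encodes the activator of the CDC7 kinase, at 9.46-fold. At the other end of the block, HSPB1, a small heat shock protein gene, rose 3.54-fold. RHBDD2, PTPN12 and MDH2, chosen after their values were seen, rose 4.73-fold, 3.40-fold and 2.94-fold. The 15 tested genes before the block had a median log2 fold change of 0.71 with 10 risen, and the 15 after it a median of -0.40 with 0 risen and 7 fallen. The list of 7q21 genes around ABCB1 straddled this edge. Of its 28 tested members 10 rose and 9 fell, against 11 and 12 when adjusted over the list alone, and all 10 that rose lay in the block; with median scaling 10 rose and 12 fell. CDK6, the largest fall on that list and chosen after its values were seen, fell 3.59-fold. The list's median was 0.12 and its mean 0.85, and it did not pass camera (adjusted p = 0.8). It passed upward without scaling (camera adjusted p = 1.77e-08), where the spread was treated as nearly known.

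**Figure D3:**
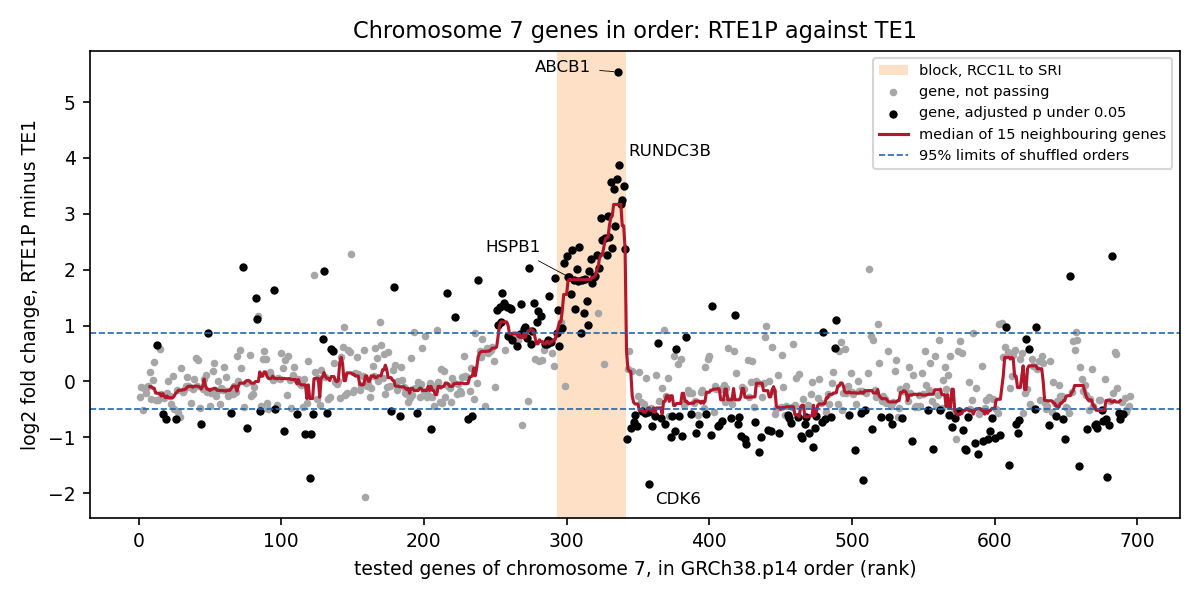
Log2 fold change (vertical axis, RTE1P minus TE1) of the tested genes of chromosome 7 in their GRCh38.p14 order (horizontal axis, rank), with passing genes in black, others in grey and the median of 15 neighbouring genes as a red line. The window median climbs through the shaded block to 3.17 near ABCB1 and turns negative from CLDN12, the 5th gene after it, while shuffled orders stayed under the dashed line at 0.86 in 95% of shuffles.

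Of the 11 tested ABC transporters of drug efflux, 2 rose and 3 fell, or 3 and 4 when adjusted over the list alone. ABCB1 rose, as did ABCC4 (1.51-fold), which was chosen after its values were seen, and ABCG2, ABCC3 and ABCC6 fell. ABCC3 fell 3.43-fold (log2 fold change -1.78, SE 0.120) and ABCC6 1.58-fold, although the mean of the ABCC6 probes gave 0.075 on the log2 scale and no call. Of this list 1 rose and 3 fell with quantile normalization and with cyclic loess, 1 and 4 with median scaling, and 3 and 2 without scaling. The list did not pass camera (adjusted p = 0.8), whose direction was down while the median and mean were above 0. The tubulins, which hold the binding site of paclitaxel, did not pass as a list either (adjusted p = 0.906). Of 19 tubulins 2 rose and 0 fell, with the same counts when adjusted over the list alone: TUBB4A rose 1.71-fold, and TUBB1 was at least 2.08-fold higher at a signal not well above background in TE1. The TUBB1 call ended with quantile normalization (adjusted p = 0.076) and with cyclic loess (0.0778). TUBB3 and TUBB, chosen after their values were seen, had log2 fold changes of -0.06 and 0.04 with SEs of 0.136 and 0.141. Of 34 microtubule-associated and tubulin-modifying proteins 2 rose, FEZ1 by 2.36-fold and MAP6 by 2.27-fold, and 0 fell; adjusted over the list alone the counts were again 2 and 0 (camera adjusted p = 0.841), and with median scaling 2 rose and 3 fell.

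Of 24 tested sterol synthesis genes 15 rose and 1 fell, against 19 and 2 when adjusted over the list alone, with a median log2 fold change of 0.70. The sterol carrier gene STARD4 rose 8.59-fold, INSIG1, a sterol sensor gene, 4.75-fold, and the sterol oxidase gene MSMO1 3.66-fold. The unfolded protein response and amino acid stress list had 16 risen and 0 fallen of 28 members, against 18 and 0 when adjusted over the list alone, and a median of 0.67. STC2 rose 8.14-fold, the cystine transporter gene SLC7A11 6.05-fold, the stress-induced gene DDIT4 3.80-fold, and HERPUD1, which acts in degradation of misfolded endoplasmic reticulum proteins, 3.51-fold. Both lists passed camera, with adjusted p = 2e-06 for sterol synthesis and 1e-06 for the stress list. With an estimated correlation between genes both camera adjusted p were 0.503. The estimated correlations were 0.028 and 0.017, close to the preset 0.01. That test rests on 2 residual degrees of freedom, so its result does not show that gene correlation made the calls. The medians of both lists stayed between 0.46 and 0.84 under quantile normalization, median scaling, cyclic loess, normexp and no scaling.

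The remaining 3 lists that passed camera did so downward, and none of them held with an estimated correlation, at 2 residual degrees of freedom. The estimated correlation was -0.024 for DNA replication, 0.495 for ribosomal proteins and 0.123 for the respiratory chain. DNA replication and G1/S genes had 4 fallen and 1 risen of 34, against 9 and 1 when adjusted over the list alone, and a median of -0.28 (adjusted p = 6.22e-05, and adjusted p = 0.503 with an estimated correlation). MCM7, a subunit of the replicative helicase, fell 1.73-fold, E2F1 1.60-fold and the cyclin gene CCNE1 1.55-fold. The member that rose, RFC2 (1.68-fold), lies among the 15 genes before the chromosome 7 block. Cytosolic ribosomal proteins had 2 fallen, RPS25 and RPL34, and 0 risen of 41, against 0 and 0 when adjusted over the list alone, with a median of -0.29 (adjusted p = 4.41e-06, and adjusted p = 0.943 with an estimated correlation). For the nuclear-encoded respiratory chain 1 of 39 fell, NDUFA8, and 0 rose, against 0 and 0 when adjusted over the list alone, with a median of -0.21 (adjusted p = 1.01e-05, and adjusted p = 0.786 with an estimated correlation). With median scaling 15 DNA replication genes, 21 ribosomal protein genes and 13 respiratory chain genes fell, and without scaling 1, 0 and 0. The DNA replication median was -0.49 with median scaling and -0.17 with cyclic loess. In the main setting it lay at percentile 0.35 of lists matched on signal. The ribosomal and respiratory lists lost their call under quantile normalization, where the adjusted p were 0.0626 and 0.253, and under cyclic loess. Spindle checkpoint and mitosis genes had 1 member risen of 31, KIF20A at 1.53-fold, 0 fallen, and 0 and 0 when adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.847) and was negative with median scaling, which moved the median of all genes by -0.21. It lay at percentile 99.96 of lists matched on signal, and was 0.215 with quantile normalization and 0.226 with cyclic loess.

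**Figure D4:**
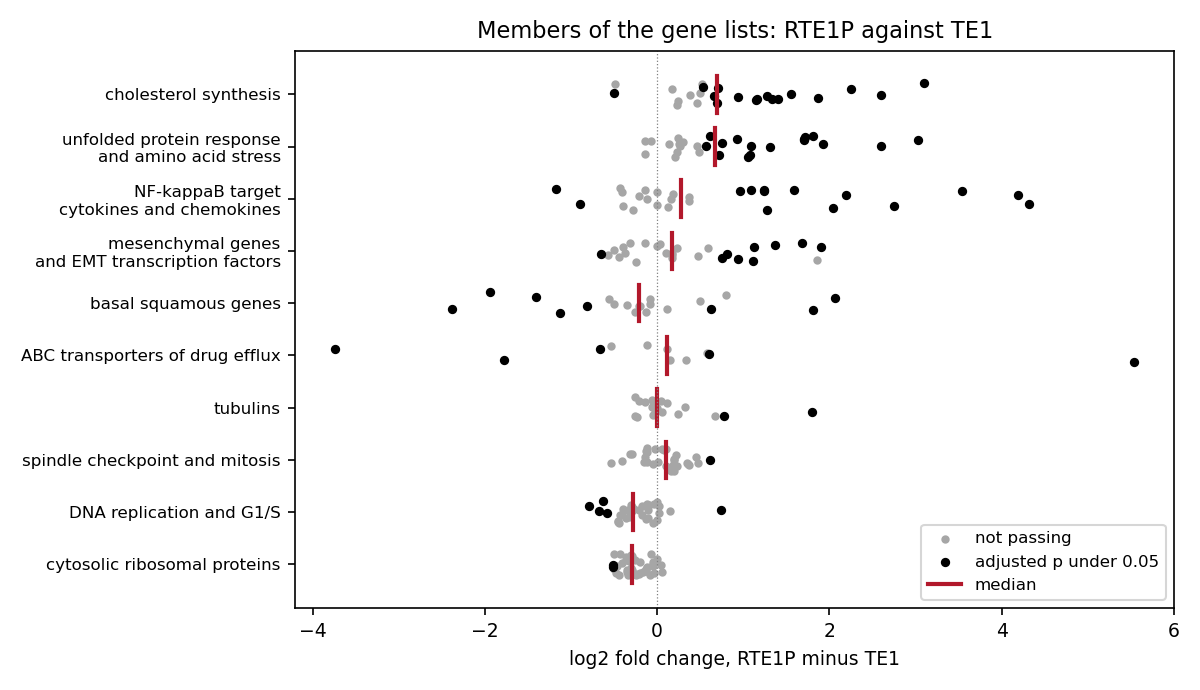
Log2 fold change (horizontal axis, RTE1P minus TE1) of the tested members of 10 gene lists, with passing members in black, others in grey and the list median as a red bar. Members measured in RTE1P only are drawn at their fitted values. The medians are 0.70 for sterol synthesis and 0.67 for the stress list, -0.28 for DNA replication and -0.29 for ribosomal proteins; the last loses its call under quantile normalization.

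Of 28 NF-kappaB target cytokines and chemokines 12 rose and 2 fell, against 14 and 5 when adjusted over the list alone (median 0.28, camera adjusted p = 0.103). The list passed camera upward with quantile normalization (adjusted p = 0.0128) and with median scaling (0.0118). It also passed without scaling (camera adjusted p = 2.31e-08), where the spread was treated as nearly known. With an estimated correlation its camera adjusted p was 0.786. TNF, CCL20 and CCL2 were among the 12, and the interleukin gene IL1A was at least 2.96-fold higher. Of 39 interferon-stimulated genes 9 rose and 1 fell, against 12 and 7 when adjusted over the list alone, and the list did not pass (adjusted p = 0.522). ISG20 rose 2.15-fold and OASL 2.25-fold, and HERC5 and OAS1 were at least 2.34-fold and 1.96-fold higher. With quantile normalization 9 rose and 7 fell, and with median scaling 8 rose and 9 fell.

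Keratins and adhesion genes changed in both directions. Of 20 basal squamous genes 3 rose and 5 fell, against 5 and 8 when adjusted over the list alone (median -0.20, camera adjusted p = 0.103). With median scaling 2 rose and 9 fell, and with no filter on dim probes the list passed downward (adjusted p = 0.0405); its adjusted p = 0.943 with an estimated correlation. KRT17 and KRT14 fell 5.20-fold and 3.85-fold, while KRT5, the usual partner of KRT14, rose 3.51-fold and the nerve growth factor receptor gene NGFR 4.19-fold. KRT14 and KRT17 have similar sequences, so their probes may share signal. Of 36 squamous differentiation genes 9 rose and 2 fell, with 9 and 3 when adjusted over the list alone (camera adjusted p = 0.522). With median scaling 8 of them rose and 5 fell, and without scaling 14 and 1. KRT4 rose 2.63-fold and ECM1 2.11-fold, and MAL fell 2.26-fold with 1 RTE1P array well above background. Of 27 mesenchymal genes and EMT transcription factors 8 rose and 1 fell, against 10 and 5 when adjusted over the list alone (adjusted p = 0.522), and their median of 0.17 was negative with median scaling, where 8 rose and 6 fell. VIM, which encodes vimentin, rose 3.75-fold, the transcription factor gene SNAI2 3.21-fold and FN1, the fibronectin gene, 2.59-fold. Of 34 epithelial junction genes 5 rose and 2 fell, against 5 and 4 when adjusted over the list alone (adjusted p = 0.8). CLDN4 and CLDN3 rose 2.40-fold and 2.09-fold and both lie near the chromosome 7 block, while the desmosomal cadherin gene DSG3 fell 2.02-fold. With median scaling 2 junction genes rose and 8 fell.

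Of 34 regulators of the BCL2 and IAP families 2 rose, PMAIP1 by 1.79-fold and BIRC2 by 1.52-fold, and 0 fell, against 1 and 0 when adjusted over the list alone (adjusted p = 0.979), and with median scaling 1 rose and 2 fell. Of 24 p53 target genes 5 rose and 0 fell, against 8 and 1 when adjusted over the list alone. SESN2, which is also on the unfolded protein and amino acid stress list, rose 2.48-fold, and CDKN1A, the p21 inhibitor gene, 2.26-fold. The p53 list had a median of 0.26 and a camera adjusted p of 0.059. It passed upward with quantile normalization (adjusted p = 0.00903), cyclic loess (0.00364), a normexp background (0.0334) and without TE1 replicate 1 (0.0262), and its adjusted p = 0.786 with an estimated correlation. Of 34 NRF2 target and glutathione genes 5 rose and 4 fell, against 5 and 8 when adjusted over the list alone (adjusted p = 0.522); with median scaling 4 rose and 9 fell. Besides SLC7A11, the glutathione transferase gene GSTA4 rose 2.72-fold and AKR1C3 2.37-fold. The lists of markers of other cell types did not pass camera. Of 6 fibroblast markers 3 rose and 1 fell (adjusted p = 0.522), with a median of 0.68 at percentile 99.8 of lists matched on signal and a fry adjusted p of 0.00531. Of 10 leukocyte markers 2 rose and 2 fell (adjusted p = 0.847), and of 8 endothelial markers 1 rose and 0 fell (adjusted p = 0.522). Adjusted over the list alone, the counts were 3 and 2, 3 and 2, and 1 and 0.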

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

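Some tests here were chosen only after the result was seen: the count of genes outside the ABC family at chromosome 7, the scan in gene order, the cyclic loess comparison, and the split of the ribosomal and respiratory tests by list. The negative-control spots, which are not used in the comparison, were brighter in RTE1P: over 153 spots per array the mean net signal was 67.2 in TE1 and 91.64 in RTE1P, a difference of 24.4. After the background subtraction that the compared signal carries, their mean lay between -2.35 and -1.69 on all 4 arrays.

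The first pattern is the chromosome 7 block around ABCB1. A local artefact of the array surface is argued against by the distance between the block's spots, whose median lay at percentile 20.53 of random probe sets. A shared change of this chromosome segment, such as a copy-number gain, may account for the block: its highest window median was 3.168, against at most 1.125 in 1000 shuffled orders. The 15 genes after SRI had a median of -0.40 with 0 risen. Every run of windows below the shuffles' lower limit on chromosome 7 lay on that side, between CYP51A1 and KMT2C. The genes after the block are therefore not an unchanged baseline. The 15 before RCC1L were lower than the block but raised, with a median of 0.71 and 10 risen. Further out, runs above the upper limit went from ASL to TMEM248 (highest window median 1.065) and from MLXIPL to STX1A (0.94). The edge at RCC1L therefore depends on the limits chosen. No DNA was measured, so a gain and a regional rise in transcription both stay open. Binding of ABCB1 transcript to the block's probes stays open too, since no probe sequences were compared. The 10 genes of the 7q21 list outside the ABC family that rose at least 2-fold would rise under it as well. For HSPB1 and DBF4 it would need more signal than ABCB1's own probe gave. That probe read 0.56 on the log2 scale in RTE1P, while HSPB1 went from 5.09 to 6.91 and DBF4 from -0.15 to 3.09. RUNDC3B and CROT read below the ABCB1 probe in RTE1P, at -0.45 and -0.68.

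The second pattern is the rise of the sterol synthesis and amino acid stress lists. A lift of dim probes by a higher RTE1P background is argued against by their members brighter than the 75th percentile, whose medians were 0.52 over 18 and 0.53 over 24 genes, both at percentile 100 of random lists matched on signal. Scaling is argued against by the medians under quantile normalization, 0.765 for sterol synthesis and 0.839 for the stress list. The lowest median under quantile normalization and median scaling was 0.459, for the stress list with median scaling. That scaling shifts genes alike, by -0.21 at the median of all genes, so this value adds little to the test. A difference in growth state or medium at harvest could also move these lists and cannot be told apart from the line, since line and culture coincide; the DNA replication list, with a median of -0.279, does not decide it. The effect of the resistant state itself is open as well and was not tested separately.

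The third pattern is the small fall of the ribosomal protein and respiratory chain lists. For the respiratory chain, a signal-dependent difference between the arrays may be the cause, since its median lay at percentile 33.1 of lists matched on signal and moved to -0.063 (-0.161 to -0.003 over resampled members) under quantile normalization. For the ribosomal proteins the percentile was 1.6, below the bound of 2.5, but the comparison is limited, since the matched genes were dimmer than the list, at 5.97 against 6.50 on the log2 scale. Cyclic loess moved the ribosomal median from -0.29 (-0.331 to -0.196) to -0.06 (-0.109 to 0.036) and ended the call because the fall itself shrank, and under quantile normalization it was -0.143 (-0.195 to -0.031). For these genes a true fall and a signal-dependent or scaling difference cannot be told apart, because the matched genes do not reach the list's signal.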

How the results depend on the processing

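Cyclic loess and the count without the chromosome 7 block were chosen after seeing the data. Against 2386 passing genes (1468 rose, 918 fell; 787 at least 2-fold, 596 and 191) and 5 lists, these counts moved by over 1.5 times, and the cause was not tested unless given. At least 2-fold, normexp gave 363 (243 rose, 120 fell), quantile normalization 370 rises and cyclic loess 359 rises. The normexp offset of 50 shrinks the folds of dim probes by construction, and its share in that drop was not tested apart. With normexp 2815 genes passed in all. Median scaling gave 3689 genes, 2549 falls and 402 falls of at least 2-fold; by construction it moved the median of all genes by -0.21. Without scaling, 2854 rose and 543 fell, 1204 changed at least 2-fold with 1043 rises, and 8 lists passed. That fit had 60500 total degrees of freedom against 4.70 and a lowest adjusted p of 2.82e-109 in limma. Its p-values and counts are therefore not comparable with the others. With no filter on dim probes 423 genes passed, 328 up and 95 down, all at least 2-fold. The mean of a gene's probes gave 3661 genes and 2289 rises, and turned ABCC6 to 0.075. Trend and robust gave 5169 genes (2676 rose, 2493 fell). An adjusted p under 0.01 gave 273 (211 and 62), all at least 2-fold. 

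camera with an estimated correlation passed 0 lists at an adjusted p under 0.05, where 5 passed with the preset correlation, and fry 13. The test with an estimated correlation rests on 2 residual degrees of freedom, at which hardly any list can pass. Its count of 0 therefore does not show that gene correlation made the 5 calls. fry does not compare a list with other genes.

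Leaving out 1 array at a time gave 0 to 3428 genes, 0 to 2540 rises and 0 to 888 falls. At least 2-fold the ranges were 0 to 1693 genes, 0 to 1394 rises and 0 to 299 falls, and 5 to 7 lists passed. The lone array left in a line is assumed to vary like the other line. Both limma counts of 0 came without an RTE1P array, with 3759 and 3216 genes at an unadjusted p under 0.05, lowest adjusted p of 0.162 and 0.071, and 3 and 3.29 total degrees of freedom against 4.70. The chromosome 7 block's median was then 2.09 and 2.01.

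The labels do not say what the replicate number marks, and 2 pairs are too few to tell whether it pairs the arrays: over 30274 probes the correlation of deviations was 0.125. With the number as a replicate block 4386 genes passed and 3083 rose, and the cancer-testis list passed (adjusted p = 0.0324). A slide block was not run, since there was 1 slide.

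Without the genes of the chromosome 7 block 2342 genes passed. This count is fixed by construction, since the block's 44 passing genes were taken out after the adjustment. With them left out 7 lists passed camera, against 5 with them. Of 2058 named-gene values under these alternatives 1665 kept direction and call, 392 lost the call and 1 reversed. In both fits without an RTE1P array every named gene lost its call, so those losses say nothing about single genes. A further 52 losses came with no filter on dim probes. Of 612 list values 576 kept their call or lack of a call, 10 lost the call and 26 gained it. Direction was compared only where a list passed in at least 1 of the fits compared, and 0 of those reversed. Medians of lists without a call could change sign, as for HOX genes (0.082, and -0.128 with median scaling) and mesenchymal genes (0.172 and -0.038). Signal over background limits the dim genes, whose folds are bounds.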

Other observations

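The scan in gene order was chosen only after the rise around ABCB1 was seen. The remaining lists did not pass camera in the 75th percentile scaling, and most held members that rose and members that fell. Of 34 TGF-beta and BMP genes 9 rose and 3 fell, against 15 and 3 when adjusted over the list alone (camera adjusted p = 0.103): ID2 rose 3.82-fold, the activin subunit gene INHBA 3.22-fold, CCN2 3.16-fold and BMP4 2.82-fold; with median scaling 5 rose and 4 fell. Of 33 WNT pathway genes 7 rose and 3 fell, against 8 and 3 adjusted over the list alone (adjusted p = 0.906), with LEF1 3.16-fold and WNT3A 2.67-fold higher and AXIN2 at least 4.09-fold higher; with median scaling 6 rose and 7 fell. Of 26 ERBB receptors, ligands and feedback genes 7 rose and 3 fell, against 11 and 5 adjusted over the list alone (adjusted p = 0.584); besides EPGN and EREG, BTC fell 3.13-fold and NRG4 rose 2.27-fold, and with median scaling 4 rose and 5 fell. Of 31 HOX genes 2 rose and 5 fell, against 4 and 6 adjusted over the list alone (adjusted p = 0.841): HOXD1 rose 3.46-fold, HOXA7 fell 3.30-fold and HOXB8 was at least 2.39-fold lower; without scaling 5 rose and 4 fell. Of 26 matrix metalloprotease and plasminogen genes 4 rose and 4 fell, against 6 and 7 adjusted over the list alone (adjusted p = 0.522), with MMP14 up 2.95-fold, TIMP3 up 2.47-fold and MMP1 down 2.28-fold; with median scaling 3 rose and 7 fell, and without scaling 5 and 3.

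Of 30 glycolysis and hypoxia genes 6 rose and 1 fell, against 6 and 2 adjusted over the list alone (adjusted p = 0.566): the glucose transporter gene SLC2A3 rose 3.25-fold and NDRG1 2.25-fold, and with median scaling 5 rose and 10 fell. Of 22 heat shock genes 4 rose and 2 fell, against 5 and 2 adjusted over the list alone (adjusted p = 0.841), with HSP90AA1 down 1.92-fold and DNAJB4 up 2.30-fold. Of 19 simple epithelial and intestinal genes 2 rose and 1 fell, against 6 and 2 adjusted over the list alone (adjusted p = 0.522): FOXA2 rose 5.03-fold and FOXA1 fell 1.82-fold, and with quantile normalization 1 rose and 2 fell. Of 19 drug-metabolising enzymes 5 rose and 4 fell, against 6 and 4 adjusted over the list alone (adjusted p = 0.979), with CYP1B1 down 2.10-fold and SULT1E1 at least 2.13-fold higher; with median scaling 2 rose and 5 fell. Of 18 stem cell-associated genes 1 rose and 4 fell, against 1 and 5 adjusted over the list alone (adjusted p = 0.635), ABCG2 and CD44 among the falls and NES 1.99-fold higher; without scaling 3 rose and 2 fell. Of 18 MHC class I genes 1 rose, NLRC5 with a log2 fold change of 0.59, and 0 fell, against 0 and 0 adjusted over the list alone (adjusted p = 0.522), and with median scaling 0 rose and 5 fell. Of 8 cancer-testis genes 2 rose, MAGEB6 and CSAG1, and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.103). The cancer-testis list passed camera upward with median scaling (adjusted p = 0.0225) and with no filter on dim probes (0.00922). It also passed without scaling (camera adjusted p = 0.00108, 5 risen), where the spread was treated as nearly known. With an estimated correlation, which was 0.752, its camera adjusted p was 0.943. Its median of 0.565 lay at percentile 48.6 of lists matched on signal, so genes of like signal rose as much. The median was 0.114 with quantile normalization and 0.055 with cyclic loess. Median, mean and camera direction differed in sign for the tubulin, BCL2 and IAP, junction, NRF2, glycolysis, HOX, stem cell, metalloprotease, ABC transporter and leukocyte lists.

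Other neighbourhoods moved together as well. Against limits of 0.86 and -0.49 from shuffled orders, 67 windows of 15 genes lay above in 4 runs and 172 below in 27 runs. Apart from the block and runs of 7 and 5 windows before it on chromosome 7, the windows above were 6 on chromosome 19 among the pregnancy-specific glycoprotein genes from PSG1 to PSG4, whose similar sequences can share signal. The windows below lay on chromosome 14 (84), chromosome 7 (50, all after the block) and chromosome 17 (38). The lowest window median, -1.08, was in the chromosome 14 run from TTC8 to ASB2, and further runs there went from GLRX5 to EIF5 (-0.89) and from SIVA1 to BTBD6 (-0.96). With windows of 25 genes, 92 lay above and 350 below. No explanation was tested for these runs.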
